A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

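The data were 8 Affymetrix yeast arrays of 1 *Saccharomyces cerevisiae* strain, 4 from control cultures and 4 from cultures with gentamicin, an aminoglycoside antibiotic. Per the labels' protocols, the treated cells had been acclimated to gentamicin and had it in the medium throughout, cells were collected in mid-log growth in YPD, and total RNA was converted with an oligo-dT primer to biotin-labelled cRNA and hybridised in 1 colour. The sample labels give the dose as 500 µg/ml, while the series' design text gives the same number in milligrams per ml, so the unit of the dose stays open. The strain is given by a number alone, without a genotype.

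The values deposited by the authors are 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes, which name no version or settings. The deposited intensities were all above 0, and on each array the mean without the lowest and highest 2% of probe sets lay near 1001, so each array had been scaled to a common mean. No detection calls were used here. Such a scaling fixes the mean of each array, so a change in the spread of signals between groups moves the median and with it the share of genes that appear higher or lower.

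The table had 9335 probe sets, of which 60 were array controls. Gene names came from the platform annotation, updated through gene identifiers to the R64 gene table, where all 6504 identifiers of probe sets with 1 gene matched. A further 328 probe sets listed several genes and 2443 listed none, and no gene was named from these. No coordinates are given, since no build is named for the deposited values. Of the 5656 genes with a probe set, 315 had more than 1, and the probe set with the highest mean log2 signal stood for the gene. By their names, the probe sets of *MFA1*, *RPL33B*, *RPL33A*, *RPS28A*, *PAU13*, *PPT1* and *HAC1* are of classes shared between similar sequences. Their signals can include related transcripts. Lists hold only genes with a probe set for which the annotation lists 1 gene. These were 80 of 137 cytosolic ribosomal protein genes, 10 of 16 thiamine genes, 30 of 36 cytosolic translation factors and 10 of 24 seripauperin genes. Further probe sets of the ribosomal protein and seripauperin lists are also of shared classes by their names, so counts for these lists are not specific to single genes.

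Signals were converted to log2 with no offset, and the 20% of genes with the lowest mean were left out, which left 4524 tested genes. Gentamicin minus control was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was a call. The groups share no replicate numbers, and no batch is given in the labels, so the model held the group alone. Of 54 gene lists, the 50 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. camera compares a list with the other tested genes, so its direction is relative to them. Array measures were compared with exact two-sided permutation tests, whose smallest possible p with 4 against 4 arrays is 0.0286.

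The genes named were set by a rule: the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap and whose higher group mean was at or above the median of the tested genes; for each called list up to 3 members with the smallest adjusted p in its direction and up to 2 called members in the other; for other lists spoken of, up to 2 called members; and auxotrophic markers, *ACT1* and control probe sets as checks. STE18, MF(ALPHA)1 and further cell type markers are named from the marker lists. *RPL33A* and *RPS28A* are named outside the rule, as paralogs of named genes, and *RPS9B* and *RPL14B* as examples of shared probe sets. The design, lists, rule and all alternatives but 2 were fixed before the data were examined. The fit was tested on simulated data for this comparison over 4524 genes with the spread of the real arrays: 68% of genes changed 1.5-fold and 93% of genes changed 2-fold were called in the right direction, with 12 false calls among 173. The simulation changed 100 genes at each size, far fewer than were called in the data. In the simulated lists, 2 of 2 shifted lists and 0 of 48 others were called. Genes were simulated independently of each other, so this cannot test how list calls behave when genes are correlated. In the data, the estimated correlation reached 0.19, for the G2 and M phase genes.

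The alternatives were quantile normalization, aligned array medians, an offset of 8.17 signal units (the value at the 5% point of all signals) before log2, no filter, a filter of the lowest 40%, no variance trend, array weights, the median over a gene's probe sets, each array left out in turn, an adjusted p under 0.01, an estimated correlation, and fry. Replacing or leaving out values far below the other 3 arrays of their group was added after the data were seen. Tables were joined with Python 3.11.15 and pandas 2.3.3 and plotted with matplotlib 3.10.9. The number of arrays limits the precision, and the median SE of a log2 difference was 0.10. The labels do not say whether the 4 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.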

Results

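Transcript levels were measured in *S. cerevisiae* grown to mid-log phase without gentamicin (controls 1 to 4, n = 4) or with gentamicin (samples 5 to 8, n = 4; 500 µg/ml per the sample labels, with the unit open as described above). Gentamicin is an aminoglycoside that binds ribosomal RNA. The comparison asked which transcripts differ between cells acclimated to the drug and untreated cells. Each array gave 9335 signals in arbitrary units. The median signal was 389 ± 7.16 (SD, n = 4) on the control arrays and 330 ± 7.06 on the gentamicin arrays, and the interquartile range of log2 signal over tested genes was 1.91 ± 0.0301 against 2.16 ± 0.0319. Both differences reached the smallest p that 4 against 4 arrays allow (exact permutation p = 0.0286, adjusted over 10 array measures 0.0714). The ratio of 3′ to 5′ *ACT1* control signal was 1.38 ± 0.107 in controls and 1.43 ± 0.0881 with gentamicin (exact permutation p = 0.486). Over tested genes, the correlation of log2 signals across genes ran from 0.955 to 0.992 within groups and from 0.908 to 0.954 between groups.

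With gentamicin, genes of ribosome assembly, of the response to mating pheromone and of the use of poor nitrogen sources were lower, while genes of the general stress response, glycolysis, the cell wall and amino acid synthesis were higher. Of 4524 tested genes, 702 were higher and 1414 were lower (limma, adjusted p under 0.05). At least 2-fold changes were seen for 164 of these, 53 higher and 111 lower. The 4 gentamicin values lay on one side of the 4 control values for 2026 genes, or 44.8%, against 2.86% by chance. The median log2 difference over all tested genes was -0.12, and distances of gene list medians from all genes are therefore given below, while the figure of gene lists shows log2 differences as measured. The split depended on scaling: quantile normalization gave 850 higher and 894 lower, and aligned array medians gave 1079 higher and 799 lower.

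The largest decreases were in genes of mating. *FIG1*, a membrane protein of mating cells, went from 1291 ± 189 in controls to 51.6 ± 7.72 with gentamicin, which lies within the range of array controls for absent transcripts (up to 89.5), so the size of its decrease is not resolved. *PRM1*, which acts in the fusion of mating cells, fell 11.9-fold, from 2965 ± 206 to 252 ± 40.5. *AGA1*, the anchor subunit of the a-agglutinin, fell 7.16-fold to 1077 ± 102. *FAR1*, an inhibitor of the cell cycle in pheromone-treated cells, fell 6.27-fold, and *FIG2*, a cell wall adhesin of mating cells, fell 4.57-fold. Of the 13 tested genes on the list of haploid and pheromone response genes, 10 were lower and 1 was higher, with the same counts adjusted over the list alone, and the list median was 0.97 log2 units below that of all genes (camera adjusted p = 0.000225, 0.046 with an estimated correlation). The exception was *RME1*, a repressor of meiosis, which rose 1.69-fold. *STE18*, the gamma subunit of the pheromone receptor's G protein, was not called (adjusted p = 0.702), and its control 3 value of 55.2 lay far below the 712 to 893 of the other controls.

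The markers of alpha cells were present in both groups and lower with gentamicin. All 4 alpha-cell markers fell (camera adjusted p = 0.000566, 0.0457 with an estimated correlation), by the same count adjusted over the list alone. *MF(ALPHA)2*, a gene of the alpha pheromone, fell 7.25-fold to 441 ± 34.6, *SAG1*, the alpha-agglutinin, fell 3.24-fold to 2118 ± 218, and *STE3*, the receptor for a-factor, fell 2.30-fold to 980 ± 63.2. *MF(ALPHA)1* fell 1.58-fold, from 19552 ± 1147 to 12365 ± 485. Of the 6 a-cell markers, *MFA1*, an a-factor gene, alone passed the signal filter and fell 4.59-fold, from 727 ± 89.7 to 164 ± 56.0. The probe set of *MFA1* is of a class shared between similar sequences. The other, dimmer probe set of *MFA1* gave a log2 difference of -1.32. Its gentamicin signal, 75.4 ± 52.5, lay within the range of controls for absent transcripts, so this size is not resolved. *BAR1* had a signal of 195 ± 6.17 in controls and 126 ± 20.9 with gentamicin, *MFA2* 183 ± 8.48 and 157 ± 17.4, and *STE6* 131 ± 48.3 and 134 ± 20.9. *AGA2* (47.8 ± 3.91 and 26.4 ± 9.81) and *STE2* (42.7 ± 12.3 and 37.8 ± 5.32) lay within the range of controls for absent transcripts. These 5 were below the filter of the gene test. Of the sporulation list, 2 genes passed the filter, and *SPS100*, a spore wall gene, rose 2.93-fold.

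**Figure D1:**
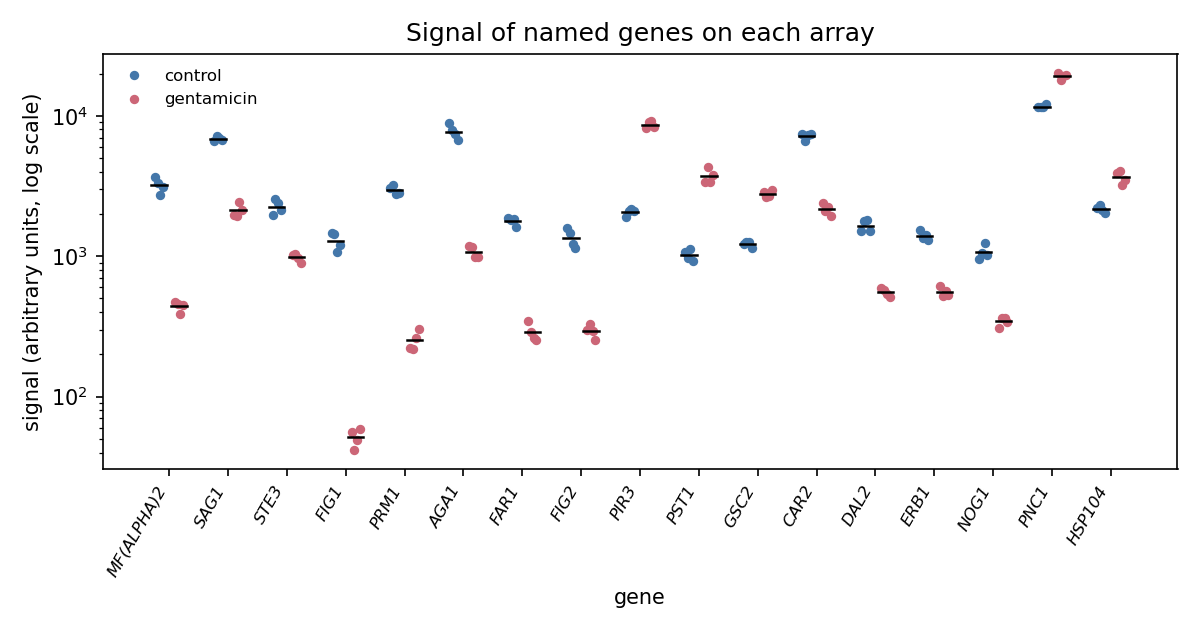
Signal of 17 named genes on each array (horizontal, gene; vertical, signal in arbitrary units on a log scale). Each point is 1 array, controls in blue and gentamicin in red, and the black lines are group means of 4 arrays. For *PRM1*, the 4 gentamicin arrays (mean 252) lie below the 4 control arrays (mean 2965), and for *PIR3* they lie above (8661 against 2065).

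Genes of ribosome assembly fell together. Of 101 tested ribosome biogenesis factors, 88 were lower and none was higher (90 lower adjusted over the list alone), with a median 0.71 log2 units below all genes (camera adjusted p = 1.96e-17, 0.0283 with an estimated correlation). *ERB1* and *YTM1*, which act together in large-subunit maturation, fell 2.53-fold to 556 ± 39.5 and 2.43-fold to 701 ± 38.3. *NOG1*, a GTPase of large-subunit assembly, fell 3.09-fold to 344 ± 27.9. *RRP12*, a factor of subunit export, fell by 1.83 ± 0.30 (SE) on the log2 scale, or -1.48 with the value of gentamicin 5, which lay far below the others, replaced by their mean. RNA polymerase I and III subunits were lower for 15 of 18 (16 adjusted over the list alone), 0.49 below all genes (adjusted p = 5.53e-05, 0.0457 with an estimated correlation), for example *RPA135*, which fell 1.83-fold, and *RPA43*, which fell 2.03-fold. Of 137 cytosolic ribosomal protein genes only 80 had a probe set with 1 gene listed, and many of these are of shared classes, for example those of *RPS9B* and *RPL14B*. Of the 80, 34 were lower (31 adjusted over the list alone), but the list median lay only 0.05 below that of all genes. The list's call (adjusted p = 0.00806) was lost with aligned array medians (0.0737) and with an estimated correlation (adjusted p = 0.311). *RPS28B* fell 1.88-fold. *RPL33B* fell 2.08-fold, while its paralog *RPL33A* had a log2 difference of -0.18. The probe sets of *RPL33B*, *RPL33A* and *RPS28A* are of a class shared between similar sequences. Mitochondrial ribosomal proteins were lower for 25 of 65 (23 adjusted over the list alone), with *MRPL10* falling 1.58-fold, and adjusted p = 0.00898, 0.123 with an estimated correlation and 0.0558 after quantile normalization. Cytosolic translation factors were not called (13 lower and 2 higher of 30, the same adjusted over the list alone, adjusted p = 0.123, but 0.0204 and called after quantile normalization): *PRT1*, a subunit of eIF3, fell 1.44-fold, whereas *ANB1*, a form of eIF5A, rose 2.26-fold. Mitochondrial translation factors were not called either (2 of 12 lower, adjusted p = 0.621), though *MEF2*, an elongation-type factor of mitochondria, fell 2.02-fold.

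Stress and folding genes rose. Of 26 general stress genes, targets of Msn2 and Msn4, 22 were higher and 1 lower (23 and 3 adjusted over the list alone), 0.79 above all genes (adjusted p = 1.09e-10, 0.0441 with an estimated correlation). *PNC1*, a nicotinamidase, rose 1.65-fold to 19202 ± 913 and *SOL4*, an enzyme of the pentose phosphate pathway, rose 2.19-fold, whereas *GRE1* fell 1.59-fold. Heat shock chaperones were higher for 17 of 23 (21 adjusted over the list alone), including *SSA4*, *SSA2* and *HSP104*, which rose 1.60-fold, 1.41-fold and 1.69-fold. The list was called (adjusted p = 2.02e-10), but not with an estimated correlation (adjusted p = 0.0526). Trehalose and glycogen genes were higher for 9 of 16, the same adjusted over the list alone, with *GDB1*, the glycogen debranching enzyme, going from 1857 ± 256 to 3683 ± 182, and *TSL1*, a subunit of trehalose synthase, rising 1.89-fold (adjusted p = 1.49e-05, 0.0874 with an estimated correlation). Stationary phase genes were higher for 7 of 11 and lower for 1 (7 and 2 adjusted over the list alone), with *SPG1* at 2.67-fold, *SPI1* at 1.82-fold and *SNZ1*, a vitamin B6 gene, at 3.19-fold (adjusted p = 0.00272, 0.0979 with an estimated correlation). Glycolysis and fermentation genes were higher for 16 of 19, the same adjusted over the list alone, 0.50 above all genes (adjusted p = 1.17e-09, 0.0283 with an estimated correlation). *PFK1*, a subunit of phosphofructokinase, rose 1.49-fold and *CDC19*, pyruvate kinase, rose 1.37-fold. Genes of the glyoxylate cycle and gluconeogenesis were not called (0 of 7 higher and 3 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.927), and *ICL1*, isocitrate lyase, fell 1.72-fold.

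Several of the largest increases were in cell wall genes. *PIR3*, a cell wall protein, rose 4.19-fold to 8661 ± 488, *PST1*, which responds to wall damage, rose 3.61-fold to 3702 ± 448, and *GSC2*, a glucan synthase subunit, rose 2.28-fold. Of 22 cell wall integrity genes, 13 were higher and 1, *CWP1*, was lower, the same adjusted over the list alone (adjusted p = 2.11e-06, 0.0283 with an estimated correlation). *NCW2*, a wall protein, rose 3.31-fold. *PPT1*, a phosphatase, was 5.71-fold higher with 1 probe set, but its other probe set gave a log2 difference of -0.83, so no direction is drawn for it. Calcineurin targets were higher for 5 of 9, the same adjusted over the list alone, with *PMC1*, a vacuolar calcium pump, rising 2.12-fold and *CMK2*, a calmodulin-dependent kinase, 1.73-fold (adjusted p = 0.00901, 0.0854 with an estimated correlation). Among the other largest increases, *NCA3* rose 3.18-fold, *TMT1* 3.01-fold, *PLN1*, a lipid droplet protein, 2.83-fold and *STR3*, a cystathionine beta-lyase, 3.15-fold. Vacuolar hydrolases were higher for 9 of 11, the same adjusted over the list alone (adjusted p = 9.31e-06, 0.0283 with an estimated correlation), with *APE1* at 1.60-fold and *PRC1*, carboxypeptidase Y, at 1.39-fold. Autophagy genes were higher for 11 and lower for 2 of 29, the same adjusted over the list alone (adjusted p = 0.00143, 0.0457 with an estimated correlation): *ATG41* rose 2.75-fold and *ATG45* fell 1.69-fold. Vacuolar ATPase genes were higher for 5 of 17 and lower for 2 (adjusted p = 0.0156, 0.117 with an estimated correlation). The tethering complexes HOPS, CORVET and GARP were not called (4 of 6 lower, adjusted p = 0.393). *VAM6* and *VPS16* of HOPS fell 1.32-fold and 1.31-fold, calls that were lost after quantile normalization (adjusted p = 0.239 and 0.299) and with aligned medians (0.105 and 0.137). For *VPS16* the call was also lost without control 4 (adjusted p = 0.0525). Of 49 vacuolar protein sorting genes, 6 were higher and 11 lower (adjusted p = 0.594).

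**Figure D2:**
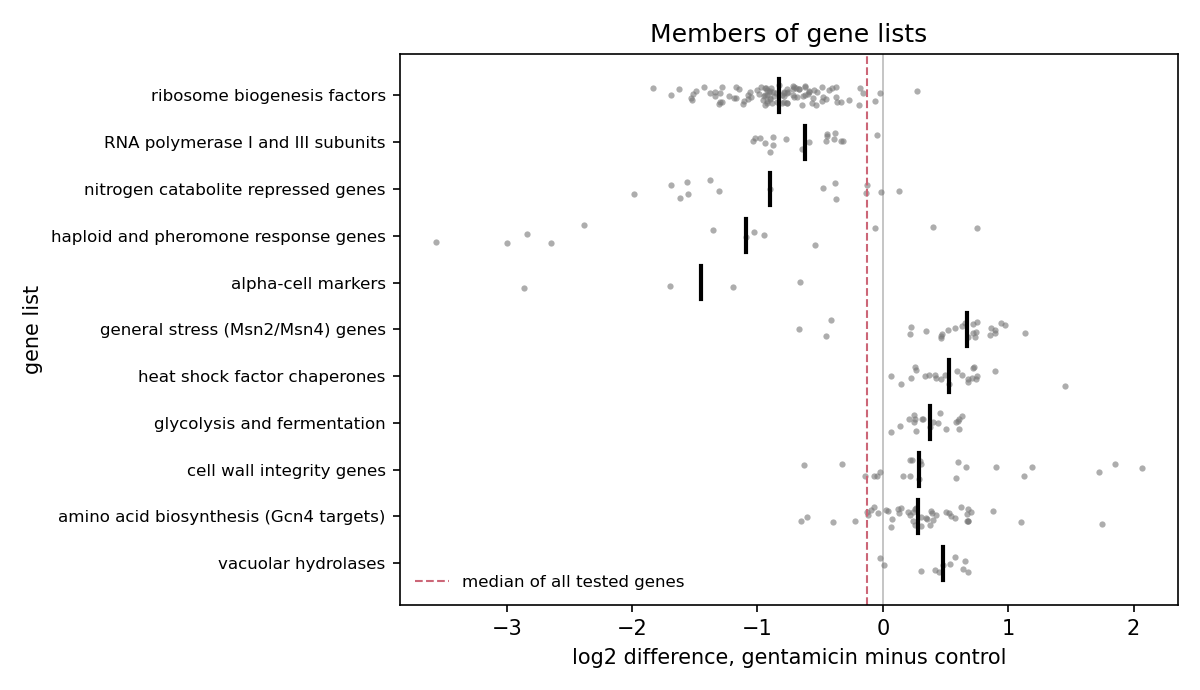
Log2 difference, gentamicin minus control (horizontal), of each tested member (grey points) of 11 gene lists (vertical), with list medians as black lines and the median of all tested genes, -0.12, as a dashed line. The ribosome biogenesis median is -0.83 and the general stress median 0.67, not relative to all genes.

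Amino acid and nitrogen genes moved apart. Of 46 Gcn4 targets of amino acid synthesis, 27 were higher and 2 lower (28 and 2 adjusted over the list alone), 0.41 above all genes (adjusted p = 1.17e-09, 0.0457 with an estimated correlation). *ARG1*, argininosuccinate synthetase, rose 3.35-fold and *LYS20*, homocitrate synthase, rose 2.14-fold, whereas *LEU1*, isopropylmalate isomerase, fell 1.57-fold. Of 15 genes under nitrogen catabolite repression, 11 were lower and none higher, the same adjusted over the list alone, 0.77 below all genes (adjusted p = 6.95e-05, 0.046 with an estimated correlation). *DAL7*, malate synthase of allantoin breakdown, fell 3.96-fold to 201 ± 17.8, *DAL2*, allantoicase, fell 2.95-fold and *DUR3*, a urea transporter, fell 2.93-fold. *CAR2*, ornithine transaminase, fell 3.32-fold and *ARO9*, an aromatic aminotransferase, fell 3.56-fold. Purine and one-carbon genes were lower for 10 of 14 and higher for 1, the same adjusted over the list alone, among them *GCV1*, of glycine cleavage, which fell 2.12-fold, and *ADE17*, which fell 1.79-fold, with *ADE3* rising 1.30-fold (adjusted p = 0.027, 0.103 with an estimated correlation). All 9 thiamine genes were lower, the same adjusted over the list alone, with *THI7*, the thiamine transporter, falling 2.23-fold (adjusted p = 0.00898, 0.0948 with an estimated correlation).

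Respiratory genes went both ways. Of 40 nuclear genes of the respiratory chain and ATP synthase, 9 were higher and 4 lower (7 and 4 adjusted over the list alone): *NDE2*, an NADH dehydrogenase, rose 3.26-fold, and *COX5B* and *CYC7*, which are known as the forms used when oxygen is scarce, rose 1.82-fold and 2.08-fold, while *CYC1*, the main form of cytochrome c in air, fell 1.94-fold. The list's call (adjusted p = 0.0345) was lost with an estimated correlation (adjusted p = 0.239), after quantile normalization, where it turned downward (adjusted p = 0.853), with the lowest 40% of genes left out (adjusted p = 0.142) and under 4 further alternatives of model, probe set and array (adjusted p from 0.0513 to 0.0686). TCA cycle genes were higher for 5 of 11, the same adjusted over the list alone (adjusted p = 0.0288, 0.179 with an estimated correlation). Proteasome genes were higher for 5 of 38 and lower for 2 (5 and 0 adjusted over the list alone; adjusted p = 0.0408, 0.118 with an estimated correlation). As measured, the median log2 difference was 0.045 for the proteasome list and 0.054 for the respiratory list. Their upward direction is thus mainly relative to all genes, whose median was -0.12. Neither was called with fry (adjusted p = 0.053 and 0.085). All 5 tested G2 and M phase genes were lower, with *CDC20*, an activator of the anaphase-promoting complex, falling 2.23-fold (adjusted p = 0.0439, 0.244 with an estimated correlation). The calls of the TCA, proteasome, vacuolar ATPase and G2 and M lists were lost after quantile normalization (adjusted p from 0.136 to 0.487), and those of the proteasome and G2 and M lists also on leaving out single arrays. With the lowest 40% of genes left out, the TCA (adjusted p = 0.0729), proteasome (0.144) and vacuolar ATPase (0.0519) calls were lost. The G2 and M call was lost with no filter (adjusted p = 0.0952) and with the median over probe sets (0.0718).

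In all, 24 of 50 lists were called, 14 upward and 10 downward relative to the other tested genes. With an estimated correlation, 11 of the 24 were called. Lists of drug and membrane genes were among those not called. For pleiotropic drug resistance, 2 of 12 were higher and 1 lower (adjusted p = 0.685): *ICT1* rose 1.30-fold and *PDR12*, a transporter of organic acids, fell 1.44-fold. Polyamine genes had 4 higher and 4 lower of 15 (adjusted p = 0.34), with *TPO2*, a polyamine exporter, rising 1.66-fold. The unfolded protein response list had 6 higher and 3 lower of 17 (adjusted p = 0.265). Its transcription factor *HAC1* rose 1.34-fold with the probe set tested, and other probe sets gave log2 differences of 0.28, 0.32 and 0.42. Only 1 dim probe set of *HAC1* fell (log2 difference -1.01). Its signal with gentamicin, 59.5, lay within the range of controls for absent transcripts, so the size of its fall is not resolved. Ergosterol genes had 1 higher and 8 lower of 26 (adjusted p = 0.864), with *ERG5* falling 2.57-fold.

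As checks, *ACT1* was 1.15-fold higher with gentamicin (adjusted p = 0.0183), a call that was lost after quantile normalization (adjusted p = 0.446) and without control 2 (adjusted p = 0.0517). *URA3*, *LYS2* and *LEU2* had mean signals of 1.62, 5.21 and 32.3 in controls and 4.87, 5.87 and 46.7 with gentamicin, within the range of controls for absent transcripts. *HIS3* was higher with gentamicin, with a log2 difference of 0.38 for the probe set tested and 1.17 for its other, dimmer probe set, so the size of its change is unclear. *ADE2* fell by 0.27 on the log2 scale (adjusted p = 0.0314), a call lost with aligned medians (adjusted p = 0.319) and without control 2, control 3, gentamicin 7 or gentamicin 8 (adjusted p from 0.0577 to 0.082). *MET17* was not called (adjusted p = 0.178). *TRP1* had 2413 ± 322 in controls and 2528 ± 882 with gentamicin, where gentamicin 5 read 1215.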

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

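Quantile normalization, the fits without 1 array and the splits of the arrays were set before the data were seen, but the use of the first 2 as tests of the patterns below, and the tests on a-cell markers, glucose exhaustion and low single-array values, were chosen after the results they bear on had been seen. Medians of gene lists are given here as measured, not relative to all genes.

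Values of 1 array far from the other 3 of the group were found in 12 of 318 groups of 4, and chance gives about 1 in 20. *FAR1* read 1619 on control 4 against a mean of 1841 on the other controls, *CAR2* 6667 on control 2 against 7368, and *SSA4* 2245 on control 4 against 2390. With gentamicin, *CDC19* read 29310 on array 7 against 26560, *GDB1* 3410 on array 7 against 3774, *VAM6* 496.8 on array 7 against 381.8 and *APE1* 12160 on array 7 against 13310. *ADE3* read 6817 on gentamicin 6 against 8729, *THI7* 2791 on gentamicin 5 against 3272, *FTR1*, an iron permease, 666.8 on gentamicin 5 against 522.1, *MET17* 4109 on gentamicin 8 against 3870, and *TRP1* 1215 on gentamicin 5 against 2965.

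Probe sets outside the gene tests carried signal too. Among 251 probe sets with several genes and a mean above 214, 63 changed (29 higher and 34 lower, limma adjusted p under 0.05). Among 464 with no gene listed, 89 changed (30 higher and 59 lower).

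On some arrays, bright probe sets (median over the other 3 arrays above 512) read more than 1 log2 unit below the lowest of those 3: 53 on gentamicin 5, 36 on control 3, 25 on control 1, 20 on gentamicin 8, 13 on gentamicin 6 and 4 or fewer on the others, while none read as far above on any array. Other bright probe sets of 11 of the affected genes had a median deviation of 0.10 (17 probe sets, the lowest -0.91), but none was of a gene affected on control 1 or gentamicin 6 and only 2, of 1 gene, on gentamicin 5, so a lower level of the other transcripts stays open. Loss of long chromosome segments on control 3 and gentamicin 5 is argued against by 566 probe sets of genes lying between affected genes up to 40 genes apart (median -0.0084). That test first used up to 20 genes, which left 2 probe sets (median -0.22), and was widened after this was seen, so loss of a few neighbouring genes stays open.

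A candidate explanation for these low values is a local defect of single arrays, if probe sets lie in rows in the order of their numbers. A first test asked whether affected numbers lie close together (permutation p = 1e-04 on control 1, control 3, gentamicin 5 and gentamicin 8, 0.018 on gentamicin 6). After it was seen, and after a spacing of about 69 was noticed on control 3 and gentamicin 5, it was replaced by a test of that spacing on control 1, gentamicin 6 and gentamicin 8 together, where 16 pairs lay 66 to 72 apart against a median of 1 in random draws (permutation p = 1e-04, the smallest that 10000 draws can give). The affected numbers of those 3 arrays may have been listed before the spacing was chosen, so this is not an independent test. The layout of the array was not used here, and no biological explanation was tested beyond these.

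The lower level of pheromone response and alpha-cell genes kept a median log2 difference of -1.15 after quantile normalization and of -1.14 or lower on leaving out any 1 array, which argues against array scaling and single arrays as its whole cause. A few a cells in the control cultures, which would set off the pheromone response of alpha cells, may account for it, and the 6 a-cell markers had a median log2 difference of -0.43 (from -2.20 to 0.13). That value does not settle it, because 5 of the 6 lay below the signal filter. The test could speak against a cells only with 3 above it, a requirement added after the markers were seen. Control cultures without a cells would leave these markers dim, so the test could not have spoken against a cells. The markers went both ways: *AGA2* and *STE2* lay within the range of controls for absent transcripts also in controls and *STE6* did not fall, while *MFA1* and *BAR1* had lower means with gentamicin. An effect of gentamicin and a variant that arose while cells were acclimated stay open as well, and neither was tested.

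Ribosome biogenesis genes were lower and general stress genes higher, and their medians lay 1.31 log2 units apart after quantile normalization (medians -0.83 and 0.67 before it), which argues against scaling as the whole cause. Exhaustion of glucose in the gentamicin cultures would raise the genes of the glyoxylate cycle and gluconeogenesis, whose 7 tested members had a median of -0.059 (95% interval over members -0.27 to 0.17). Of 8 tested hexose transporters, 1 was higher and 2 were lower (camera adjusted p = 0.927), with *HXT5* rising 1.71-fold and *HXT1* falling 1.40-fold. The interval covers genes, not cultures, so these values do not exclude a lower glucose level. Slower growth and a direct response to gentamicin stay open, and neither was tested.

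Chance in how the arrays fall into groups was checked with all 35 splits into 4 and 4. For the 702 genes higher, the 1414 lower and the 164 changed at least 2-fold, 1 of 35 splits, the real one, gave as many. The highest of the others was 0. These counts come from the same fit, and every other split mixes the groups, which turns their difference into spread. The result argues against chance in the grouping of these arrays only. It cannot address chance between cultures, since the samples of a group may come from the same culture. For the 24 gene lists, 1 of 35 splits gave as many, with 21 as the highest of the others. The 16 splits that put 3 arrays of one group with 1 of the other gave 11 to 21 lists, and the 18 splits with 2 of each gave 0. With an estimated correlation the real split gave 11 lists and the others gave 0. In the other splits the group difference becomes spread shared by genes of a list, which can raise the estimated correlation. The 0 therefore adds no further support.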

How the results depend on the processing

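Replacing or leaving out low values of single arrays was chosen after the data were seen, as was which lists without a call are described here. Of the 2116 genes called, 1478 were called in the same direction after quantile normalization and 1501 with aligned medians. The number of genes lower was 894 after quantile normalization, 799 with aligned medians and 915 at an adjusted p under 0.01. Aligned medians gave 1079 genes higher, and the lowest 40% left out gave 101 genes changed at least 2-fold. The shift in calls under the 2 scalings follows their construction, since the median difference over all tested genes moved from -0.12 to -0.02 and 0.02. Leaving out the lowest 40% reduced the tested genes from 4524 to 3393 and the 2-fold changes from 164 to 101, a larger share. Fewer tested genes thus account for only part of it, and 2-fold changes were more frequent among the dimmer genes left out. The fewer genes at 0.01 follow from the threshold. An estimated correlation called 11 lists and fry 38, and fry tests lists without comparing them with other genes. Leaving out 1 array gave 603 to 693 genes higher, 1209 to 1360 lower, 162 to 176 changed at least 2-fold and 21 to 24 lists. Of the 24 called lists, 17 were called under every alternative of scaling, offset, filter, model, probe set and array, and 7 lost the call under at least 1. List medians here are log2 differences as measured, not relative to all genes. The respiratory list turned to a median of -0.039 after quantile normalization, and the glyoxylate list, not called, to 0.087 with aligned medians. fry gave a downward direction for the vacuolar protein sorting list (-0.042) and the drug resistance list (-0.048), for which camera gave an upward one. Of the 26 lists not called, the direction turned for 9 under at least 1 alternative other than the set test. For genes not called, *MET17* turned to 0.020 and *TRP1* to 0.13 with aligned medians. *TRP1* was 0.13 with array weights, 0.31 (adjusted p = 0.0238) with low values replaced, 0.31 (adjusted p = 0.044) with them left out, and -0.14 to 0.31 on leaving out 1 array, the highest without gentamicin 5. Where not stated, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Signals under about 90 lie within the range of controls for absent transcripts, so changes of such genes are not resolved.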

Other observations

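Some further gene groups were measured and not called. Of 13 genes of the G1 and S phases, 6 were lower and none higher (camera adjusted p = 0.123), with *POL1*, the catalytic subunit of DNA polymerase alpha, falling by 0.58 on the log2 scale. Of 15 genes of the Zap1 zinc regulon, 9 were lower and 1 higher (adjusted p = 0.265), with *ZRT1*, a zinc transporter, falling 1.39-fold with the probe set tested, while its other 3 probe sets gave log2 differences from -0.85 to -0.12. Of 24 seripauperin genes 10 had a probe set with 1 gene listed. Of these 10, 3 were higher and 1 lower (adjusted p = 0.0641), with *PAU13* rising 1.28-fold on a probe set of a class shared between similar sequences. The seripauperin list was called after quantile normalization (adjusted p = 0.0253), with no filter (0.0460) and with array weights (0.0463), and its adjusted p over the alternatives of scaling, filter, model, probe set and array reached 0.166.

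The 10 probe sets for ribosomal RNA were all higher in mean with gentamicin. Their geometric mean signal was 43.4 ± 7.94 (SD, n = 4) on the control arrays and 65.7 ± 12.7 on the gentamicin arrays (exact permutation p = 0.0571, adjusted over 10 array measures 0.114), so the difference was not past the threshold. Both means, and those of most of the 10 probe sets, lay within the range of controls for absent transcripts, so the difference is not resolved. The cRNA was primed with oligo-dT, so these signals do not measure the amount of ribosomal RNA in the cells.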
